A study of Homo sapiens with 9 samples.

How the data were processed

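RNA from 9 samples of stomach tissue was sequenced after poly-A selection, per the labels' protocols, with 1 library per sample: 3 from normal stomach (NL), 3 from Ménétrier's disease (MD) and 3 from juvenile polyposis syndrome (JPS). RNA was isolated with a column kit, and a commercial provider fragmented the mRNA and made either an NEB or a strand-specific library, per the labels' protocols, which do not state which. CASAVA and the builds GRCh37 and hg19 were named without a role, per the submitters' processing notes. The aligner, the counting program, the annotation release and whether strand was used in counting were not given in the sources used here, so reads from a gene and an overlapping antisense gene could not be told apart. The authors deposited a table of raw counts per gene, whole numbers with a different total in each library, with the length, coordinates and symbol of 48162 genes, of which 189 repeated a symbol of another gene. The authors also deposited a table of FPKM values, which are scaled for gene length and library size. Each FPKM value equalled the count divided by the gene length and by the library's total on the usual FPKM scale, with a largest relative difference of 4.984e-12 and 0 zeros differing between the tables. Coordinates are given as in the deposited tables, whose positions are on GRCh37 (hg19). The reference annotation at hand was on another build and was not used.

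Libraries were assigned to groups from their labels, and the column names of the deposited tables matched these labels. Whether each library came from a different individual was not given in the sources used here, and each was treated as an independent sample. The deviations of same-numbered libraries from their group means had correlations on both sides of 0, so the numbers were not treated as pairs. Every pair of libraries differed by more than counting noise: the smallest chi-square per degree of freedom between libraries of a group was 50.5, for NL replicates 1 and 3.

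The tests were run on the deposited counts in R 4.3.3 with edgeR 4.0.16. XIST, its antisense gene and the genes of the Y chromosome, 462 genes in all, were left out of the tests and of the tables because the samples came from persons. Genes with low counts were removed with filterByExpr by group, which left 17980 genes. TMM factors scaled the libraries, and a robust quasi-likelihood model with group as its term was fitted to all 9 libraries together. The contrasts MD against NL, JPS against NL and MD against JPS were tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. CPM values, counts scaled to library size, were computed with TMM-scaled library sizes. They are given as the mean ± SD of the 3 libraries of a group. Log2 fold changes are given with standard errors, computed as the size of the log2 fold change divided by the square root of F. A gene is said to have risen or fallen only where its adjusted p passed the threshold.

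Before the data were examined, 42 gene lists with 719 members were fixed from general knowledge. They covered Hedgehog signalling and other pathways, cell types of the stomach wall, other cell types that the tissue could hold, and signs of RNA quality. Of the members, 715 matched a gene by symbol or older symbol and 632 were tested. A list needed 3 tested members, which left 41 lists. Each list was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over the lists. The same test was run with a correlation estimated per list, and fry was run as a directional test that does not compare a list with other genes. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

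The genes named in the text followed a rule that was also fixed before the data were examined. They were the 10 largest rises and the 10 largest falls among genes past the threshold with a mean log2 CPM of at least 2 whose groups did not overlap. For each list the rule took the 4 members with the smallest p. All members were allowed for Hedgehog signalling, and 11 further genes were always given. HLA genes, immunoglobulin and T cell receptor segments and genes without a symbol were not named. Reads of near-identical copies may have been divided by the authors' counting, so values of the pepsinogen A, metallothionein, CEACAM and alpha globin genes and of CKMT1A and HSPA1B are uncertain to that extent.

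The alternatives were other size factors (RLE and upper quartile), no filter on low counts, and a stricter filter of 10 counts in every library of a group with a mean log2 CPM of 1. They also included DESeq2 1.42.0, limma-voom with quality weights, a fit of only the 2 groups compared, the replicate number as a block, and limma on log2 of the deposited FPKM with 1 or 0.1 added. A stricter adjusted p of 0.01, a further log2 fold threshold of 1, and each library left out in turn completed the planned set. After the data were seen, fits without NL replicate 2 and JPS replicate 2 together, and without the 13 mitochondrially encoded genes, were added. The test was checked on counts simulated from the mean levels, dispersions and library sizes of the 9 libraries, with 50 genes changed at each of 4 fold sizes. For MD against NL, 0 of 50 genes changed 2-fold, 7 changed 4-fold, 27 changed 8-fold and 31 changed 16-fold were called, with 2 calls among unchanged genes. For JPS against NL the numbers were 0, 8, 21 and 37, with 4 calls among unchanged genes, and for MD against JPS 0, 8, 23 and 31, with 2. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.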

Results

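The series compared 3 samples of stomach tissue with Ménétrier's disease (MD), a rare overgrowth of the gastric mucosa, 3 with juvenile polyposis syndrome (JPS), an inherited disorder that forms polyps, and 3 of normal stomach (NL). Its title concerns Hedgehog signalling in MD. The deposited counts totalled 18001903, 9903871 and 15606218 in NL replicates 1 to 3, 26187019, 27896756 and 29108837 in MD replicates 1 to 3, and 19966371, 16265878 and 27548357 in JPS replicates 1 to 3. Between 13621 (JPS replicate 2) and 27095 (MD replicate 3) genes had at least 1 count, and 17980 genes were tested.

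The makeup of the libraries differed between and within groups. Pepsinogens and gastric lipase, the digestive enzymes of chief cells, took 26.0%, 49.0% and 15.2% of the counts in the NL libraries, 7.82%, 2.22% and 0.329% in the MD libraries, and 4.64%, 0.555% and 5.45% in the JPS libraries. Mitochondrially encoded genes took 90.0% of the counts of JPS replicate 2, which left 1627711 counts from other genes, and between 5.19% and 23.0% in the other 8 libraries. In a principal component analysis of log2 CPM, the leading component held 46.3% of the variance and set JPS replicate 2 apart, and the next held 28.0% and set NL replicate 2 apart. Counts of changed genes are therefore also given without these libraries, an alternative added after the data were seen.

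**Figure D1:**
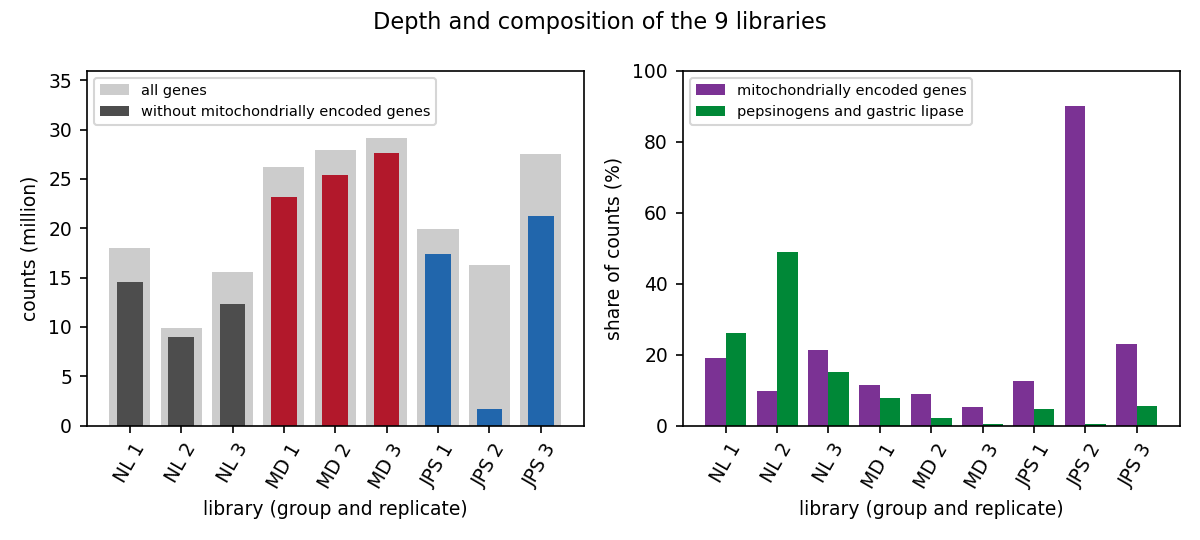
Left, counts in each of the 9 libraries, over all genes in grey and without mitochondrially encoded genes in the colour of the group; JPS replicate 2 keeps 1627711. Right, the percent of counts in mitochondrially encoded genes and in pepsinogen and lipase genes per library; NL replicate 2 has 49.0% in the latter.

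MD was compared with NL to find which genes differ between the diseased and the normal stomach. Under the rule for naming genes, CEACAM5 and REG4 had the largest rises in MD and FKBP5 the largest fall. CEACAM5, an adhesion protein of gut epithelium (ENSG00000105388, chromosome 19, 42212504 to 42233718), rose from 3.04 ± 2.99 to 653 ± 545 CPM (SD, n = 3 per group), a log2 fold change of 7.83 ± 1.09 (SE). REG4, a secreted lectin of intestinal-type cells (ENSG00000134193, chromosome 1, 120336641 to 120354283), rose from 0.814 ± 0.366 to 190 ± 158 CPM, a log2 fold change of 7.79 ± 1.08. FKBP5, a co-chaperone induced by glucocorticoids (ENSG00000096060, chromosome 6, 35541362 to 35696360), fell from 263 ± 158 to 10.8 ± 2.49 CPM, with a log2 fold change of -4.60 ± 0.58.

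In this comparison of MD against NL, 338 of 17980 genes passed the threshold with edgeR, 257 higher and 81 lower in MD, and 319 of the 338 were protein coding. The other large rises were of MMP3, a matrix-degrading protease (7.34 ± 1.34), C12orf36 (6.72 ± 0.85), SLC6A20, a proline transporter (6.47 ± 0.76), MYEOV (6.45 ± 0.79), CEACAM6 (6.32 ± 1.17), MUC13, a membrane mucin (5.75 ± 0.88), COL17A1, a collagen of epithelial anchoring (5.45 ± 0.92), and FUT3, which makes Lewis antigens (5.45 ± 0.92). The other large falls were of HIF3A (-4.50 ± 0.92), the complement component C7 (-4.49 ± 0.81), the neurotrophic factor NRTN (-4.45 ± 0.98), the cell cycle inhibitor CDKN1C (-4.21 ± 0.83), the potassium channel KCNJ11 (-4.17 ± 0.92), TSC22D3 (-3.90 ± 0.45), the clock gene PER1 (-3.88 ± 0.68), KLF15 (-3.86 ± 0.66) and APOLD1 (-3.61 ± 0.59). FKBP5, TSC22D3, PER1 and KLF15 are all known to be induced by glucocorticoids. The groups did not overlap in 33.4% of genes, where chance gives 10%.

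The count of 338 rested on each library to some degree: it was 6 without NL replicate 1, 90 without NL replicate 3, 86, 37 and 31 without MD replicates 1, 2 and 3, 191 without JPS replicate 3, and 727 without JPS replicate 2. Without NL replicate 2 and JPS replicate 2 together it was 1777, of which 324 were among the 338. Among the 20 genes with the largest changes, TSC22D3 passed the threshold without each of the 9 libraries in turn, and each of the other 19 lost its call without at least 1 library. FKBP5 had an adjusted p of 0.0511 without MD replicate 3, and CEACAM5 and REG4 had 0.0890 without NL replicate 1. The genes past the threshold that are named from the lists each lost the call without NL replicate 1, with adjusted p from 0.0614 (OASL) to 0.187 (EREG).

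**Figure D2:**
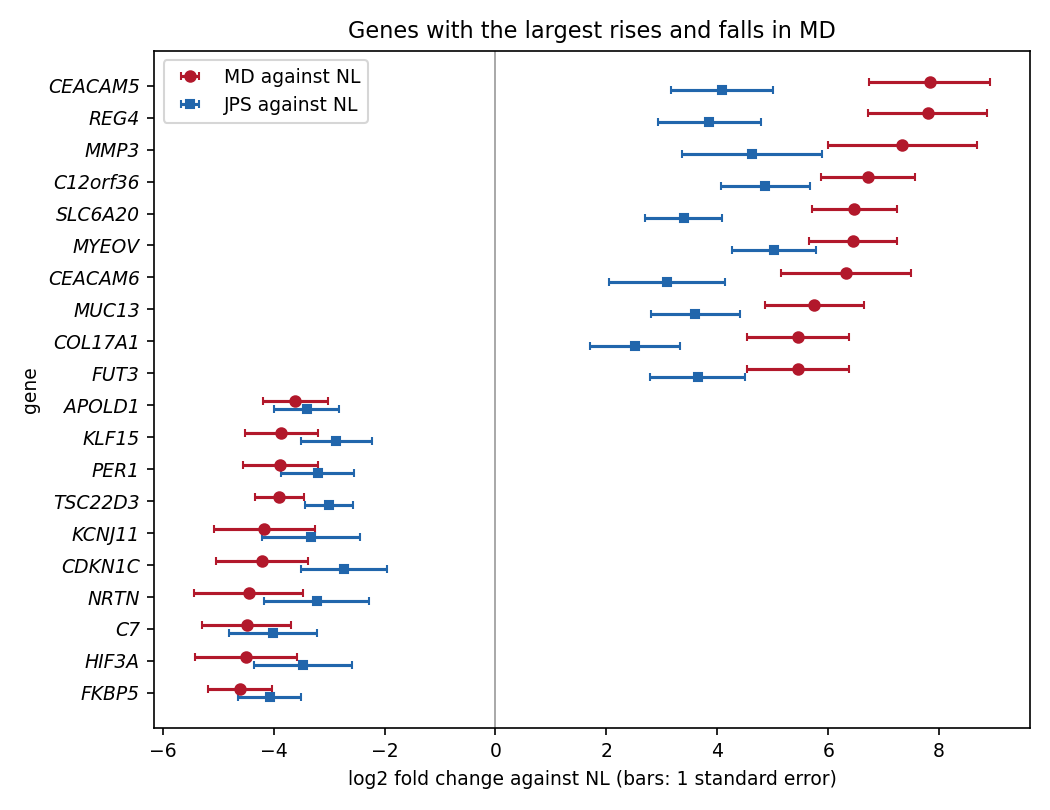
Log2 fold change with its standard error of the 10 largest rises and the 10 largest falls of MD against NL, with the value of JPS against NL beside each (n = 3 libraries per group). CEACAM5 has 7.83 in MD and 4.08 in JPS, and FKBP5 has -4.60 in MD; no gene passed the threshold in JPS against NL.

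Among the epithelial gene groups, markers of foveolar (surface mucous) cells were higher in MD than in NL, and the lists of chief, parietal and endocrine cell markers ranked lower, the parietal list with libraries that overlapped between the groups. None of these 4 lists passed with an estimated correlation (adjusted p from 0.302 to 0.584). Of 17 foveolar markers, 2 rose over all genes tested and 14 adjusted over the list alone, with a median log2 fold change of 3.23. TFF1, a peptide secreted with mucus, rose from 234 ± 175 to 7072 ± 775 CPM, a log2 fold change of 4.92 ± 0.94, and GPX2 rose by 3.71 ± 0.57. The foveolar list passed camera with an adjusted p of 4.21e-11, and had an adjusted p = 0.302 with an estimated correlation. Of 24 intestinal metaplasia markers fixed, 12 were tested. The filter could keep a gene near 0 in NL for its counts in other libraries, so the 12 do not stand for the whole list. Of the 12, 3 rose over all genes tested (REG4, CEACAM5 and MUC13) and 8 were higher and 1 lower adjusted over the list alone. The list had a camera adjusted p of 0.00135 (adjusted p = 0.468 with an estimated correlation). In NL replicates 1 to 3 its median log2 CPM was low, at 0.43, 1.20 and 0.57. The median of this list was 3.29, and 1.87 without MD replicate 3, which stood apart with a median log2 CPM of 5.98 against 1.47 and 2.23 in MD replicates 1 and 2. SPINK4, a goblet cell peptide of the same list, had no counts in NL and 0.956, 4.37 and 49.5 CPM in MD replicates 1 to 3, a mean of 18.3 CPM that rests on MD replicate 3. Of 14 markers of mucous neck cells and metaplasia, 1 rose over all genes and 6 were higher and 1 lower adjusted over the list alone. The 1 that rose was GPX2, which is also in the foveolar list and was counted there. The list had a camera adjusted p of 0.0103 (adjusted p = 0.584 with an estimated correlation).

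Of 12 chief cell markers, 0 passed over all genes with edgeR, and 5 were lower and 1 higher adjusted over the list alone, with a median of -2.99. The median log2 CPM of the chief cell list was 5.70, 3.86 and 0.19 in MD replicates 1 to 3, so MD replicate 3 stood apart, and the median log2 fold change was -4.39 without MD replicate 1 and -2.49 without MD replicate 3. BHLHA15, a regulator of secretory cells, had -2.69 ± 0.67, and PDIA2 had -3.45 ± 0.93. The chief cell list passed camera with an adjusted p of 8.46e-06 (adjusted p = 0.468 with an estimated correlation). Of 17 parietal cell markers, 0 passed over all genes and 0 adjusted over the list alone, and the median was -2.28 (camera adjusted p = 0.00503, and adjusted p = 0.584 with an estimated correlation). The median log2 CPM of the parietal list was 7.31, 5.401 and 7.38 in NL replicates 1 to 3 and 6.84, 5.85 and 0.68 in MD replicates 1 to 3, so MD replicate 3 stood apart and NL replicate 2 lay below the other MD libraries. The median log2 fold change of this list was -3.43 without MD replicate 1 and -1.69 without MD replicate 3. The parietal markers VEGFB, at -2.37 ± 0.67, and CA2, at 2.99 ± 0.89, lay on opposite sides of 0. Of 16 endocrine cell markers, 0 passed over all genes and 0 adjusted over the list alone, with a median of -1.77 (camera adjusted p = 9.99e-04, and adjusted p = 0.584 with an estimated correlation). Of the genes fixed for all comparisons, MUC5AC, the main surface mucin, had 3.50 ± 1.24, the proton pump subunits ATP4A and ATP4B had -2.82 ± 2.04 and -2.28 ± 2.02, and PGC had -4.24 ± 1.56; none of these passed. PGC was -2.76 without NL replicate 2, and ATP4A and ATP4B were -4.91 and -4.00 without MD replicate 1. Without NL replicate 2 and JPS replicate 2, MUC5AC had an adjusted p of 0.0456.

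Among the immune and inflammatory groups in MD against NL, 6 of 25 interferon response genes rose over all genes tested and 8 adjusted over the list alone. OASL rose by 4.10 ± 0.45, OAS1 by 3.55 ± 0.41, IFI27 by 2.95 ± 0.51 and MX2 by 1.77 ± 0.32 on the log2 scale. The interferon list passed camera with an adjusted p of 5.03e-07 (adjusted p = 0.302 with an estimated correlation). Of 21 genes of epithelial and neutrophil-recruiting inflammation, 4 rose over all genes, and 10 were higher and 2 lower adjusted over the list alone. These 4 were IL1RN (4.24 ± 0.62), IL1B (5.29 ± 0.92), PTGS2 (6.37 ± 1.19) and CXCL1 (4.47 ± 0.98), and the list had a camera adjusted p of 2.03e-05 (adjusted p = 0.302 with an estimated correlation). Of 11 neutrophil markers, 0 passed over all genes and 0 adjusted over the list alone. Their camera adjusted p was 0.0328 (adjusted p = 0.584 with an estimated correlation), and 0.127 without NL replicate 1, 0.115 without NL replicate 3 and 0.1001 without MD replicate 3.

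In the stromal and signalling groups of MD against NL, enteric neuron and glia markers had a median of -2.91, with 0 of 11 past the threshold over all genes and 8 lower adjusted over the list alone (camera adjusted p = 5.03e-07, and adjusted p = 0.302 with an estimated correlation). Of 9 adipocyte markers, LEP passed over all genes, with a mean of 0.993 CPM in NL and no counts in MD, and 3 were lower adjusted over the list alone (median -2.07, camera adjusted p = 0.00755, and adjusted p = 0.468 with an estimated correlation). The LEP call ended without 8 of the 9 libraries, each left out in turn, and this 1 gene of low counts cannot assign the difference to adipocytes. The adipocyte list had an adjusted p of 0.218 with the stricter filter and 0.0746 with limma-voom, and its libraries overlapped, with median log2 CPM of 1.56, 3.35 and 2.13 in NL and 2.30, 2.13 and 0.16 in MD. Of 15 smooth muscle markers, 0 passed over all genes and 0 adjusted over the list alone (median -0.97, camera adjusted p = 0.0303, and adjusted p = 0.584 with an estimated correlation). The smooth muscle list had a median of -0.11 and an adjusted p of 0.672 without NL replicate 2, and an adjusted p of 0.0859 without MD replicate 1, 0.189 without MD replicate 3 and 0.0847 without JPS replicate 2. Of 20 fibroblast and matrix genes, VCAN (2.75 ± 0.44) and COL3A1 (2.39 ± 0.47) rose and C7 and COL14A1 (-1.57 ± 0.33) fell, with 8 higher and 3 lower adjusted over the list alone. The fibroblast list had a camera adjusted p of 0.0303 (adjusted p = 0.584 with an estimated correlation). Its camera adjusted p was 0.144 without NL replicate 1, 0.115 without NL replicate 3, 0.1001 without MD replicate 3 and 0.0600 without JPS replicate 2. With the replicate number as a block it was 0.0603. Of 18 genes of TGF-beta signalling, 0 passed over all genes and 7 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00654, and adjusted p = 0.302 with an estimated correlation). All 25 proliferation genes had positive values with a median of 2.61, and 0 passed over all genes and 7 were higher adjusted over the list alone (camera adjusted p = 5.74e-06, and adjusted p = 0.584 with an estimated correlation). MD replicate 1 lay within the NL libraries, with a median log2 CPM of 1.09 against 4.39 and 3.77 in MD replicates 2 and 3 and 1.63, 0.38 and 0.95 in NL. EPHA2 (2.92 ± 0.56) was the 1 of 16 MAPK feedback and target genes that rose over all genes, with 6 higher adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.554 with an estimated correlation).

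TGFA, the EGF receptor ligand, had a log2 fold change of 2.10 ± 0.64 in MD against NL with an adjusted p of 0.122, and an adjusted p of 0.0199 without NL replicate 2 and JPS replicate 2. EREG, another ligand, had means of 0.0492 CPM in NL, 2.33 ± 1.53 CPM in MD and 0.0111 CPM in JPS, with an adjusted p of 0.0451 for MD against NL. EGFR had 0.06 ± 0.79, SMAD4 had -0.52 ± 0.47 and BMPR1A had -0.11 ± 0.38, and none of the 3 passed; EGFR was -0.37 without NL replicate 2, and BMPR1A was 0.12 without NL replicate 3. Across the 41 lists tested, 22 passed camera in MD against NL, 11 higher and 11 lower. Splits that mixed the NL and MD libraries also passed 8 to 20 lists, so a camera pass at the preset correlation is not particular to the real groups. With an estimated correlation 0 lists passed in any of the 3 comparisons. With fry, which tests whether the genes of a list move on balance in one direction without comparing them with other genes, 6 lists passed in MD against NL, 1 in JPS against NL and 0 in MD against JPS.

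Hedgehog genes were compared because the title names the pathway. SHH, the secreted ligand (ENSG00000164690, chromosome 7, 155592680 to 155604967), rose in MD from 8.58 ± 2.90 to 112 ± 40.1 CPM (SD, n = 3 per group), a log2 fold change of 3.69 ± 0.69 against NL (adjusted p = 0.0305). The 3 MD libraries had 77.4, 102 and 156 CPM of SHH and the 3 NL libraries had 8.40, 5.77 and 11.6. DISP1, which releases the ligand, rose by 1.96 ± 0.35 (adjusted p = 0.0255), and FOXL1, a transcription factor gene that responds to Hedgehog in gut mesenchyme, rose by 2.46 ± 0.50 (adjusted p = 0.0384). The transcription factor GLI1 had 0.54 ± 0.62 (adjusted p = 0.709) and the receptor PTCH1 had 0.58 ± 0.49 (adjusted p = 0.582), with 95% intervals from -0.83 to 1.92 and from -0.49 to 1.66. HHIP, an inhibitor and target, had 2.93 ± 0.70 (adjusted p = 0.0636), and SCUBE2, which helps release the ligand, had -3.13 ± 0.81 (adjusted p = 0.0809). In JPS against NL, FOXL1 had 2.67 ± 0.51 and HHIP had 2.34 ± 0.69, and neither passed. FOXL1 had -0.21 ± 0.47 in MD against JPS. The FOXL1 call in MD against NL ended without 7 of the 9 libraries, each left out in turn, and the DISP1 call without 5.

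Of 23 Hedgehog signalling genes tested in MD against NL, 3 rose over all genes tested, and 5 were higher and 1 lower adjusted over the list alone. The list did not pass camera (adjusted p = 0.355) and had 12 positive members. In JPS against NL, 0 of the 23 passed over all genes with edgeR, and 4 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.123); it was 0.0187 without NL replicate 2. In MD against JPS, 0 passed over all genes and 0 adjusted over the list alone. There the median of 0.087 and the mean of 0.12 were positive, while camera ranked the list lower (adjusted p = 0.658), and higher without MD replicate 3 (0.849). That median turned negative without MD replicate 1 (-0.21) or JPS replicate 2 (-0.035). Of 14 Hedgehog target genes, a list of its own, FOXL1 rose in MD against NL over all genes tested, and 3 were higher and 2 lower adjusted over the list alone. Their median of 0.44 was positive and their mean of -0.034 negative. The median was 0.20 without MD replicate 1 and 0.21 without NL replicate 1. Camera ranked the target list higher (adjusted p = 0.670), and lower without NL replicate 1 (0.735) or NL replicate 3 (0.951). In JPS against NL 0 target genes passed over all genes, and 2 were higher and 1 lower adjusted over the list alone (adjusted p = 0.190, and 0.0200 without NL replicate 2). In MD against JPS 0 passed by either count (adjusted p = 0.145). SHH had 29.0 ± 21.7 CPM in JPS, with 1.77 ± 0.64 for JPS against NL (adjusted p = 0.328) and 1.92 ± 0.64 for MD against JPS (adjusted p = 1), so neither passed. JPS replicates 1 to 3 had 48.1, 5.45 and 33.4 CPM of SHH. Without NL replicate 2 and JPS replicate 2, SHH had 2.01 ± 0.38 in JPS against NL (adjusted p = 0.0867) and 1.44 ± 0.34 in MD against JPS (adjusted p = 0.422). Neither passed there. The SHH call in MD against NL had an adjusted p of 0.128, 0.0802 and 0.0689 without NL replicates 1, 2 and 3, and of 0.0568, 0.0819 and 0.102 without MD replicates 1, 2 and 3. Without NL replicate 2 and JPS replicate 2 together, SHH had 3.45 ± 0.38 with an adjusted p of 0.00710, and 7 of 24 Hedgehog genes passed. Beside SHH, DISP1 and FOXL1 these were IHH (1.65 ± 0.39, adjusted p = 0.0452), SCUBE1 (1.96 ± 0.36, 0.0237), FOXF1 (1.10 ± 0.26, 0.0448) and FOXF2 (1.26 ± 0.20, 0.0160), while PTCH1 had 0.17 ± 0.34 and GLI1 had 0.91 ± 0.48 and neither passed.

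**Figure D3:**
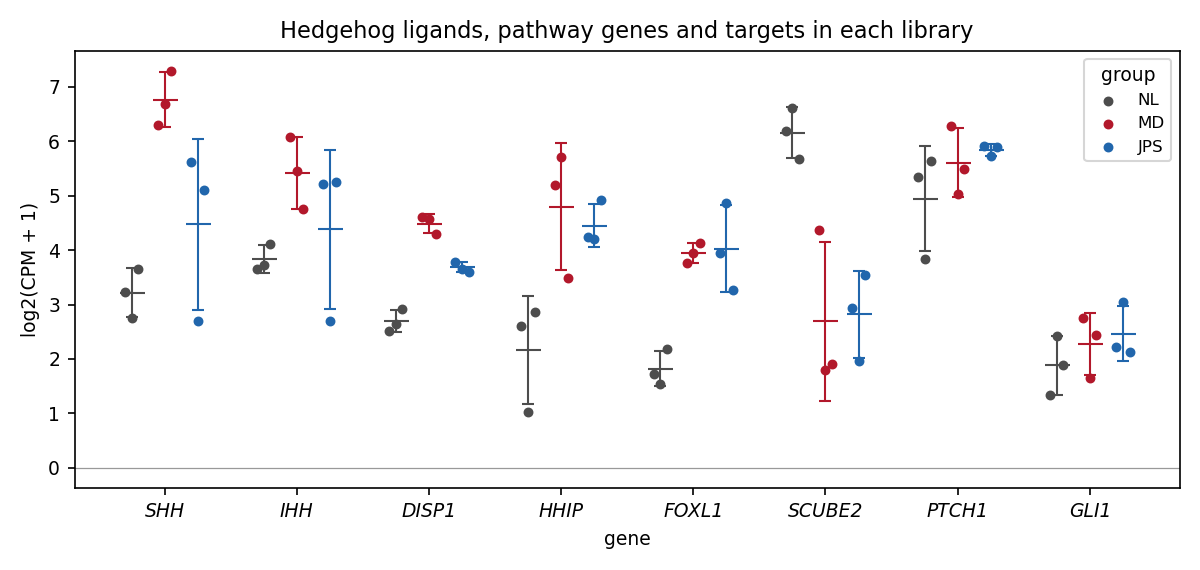
Log2 of CPM plus 1 of 8 Hedgehog signalling genes in each of the 9 libraries (points), with the mean and SD of each group of 3. SHH has a mean of 8.58 CPM in NL, 112 in MD and 29.0 in JPS, while GLI1 has 2.87, 4.10 and 4.77 CPM.

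JPS was compared with NL to set another disorder of gastric overgrowth beside MD. Camera ranked the interferon response, foveolar and inflammation lists higher in JPS than in NL, and the enteric neuron and endocrine lists lower. None of these 5 lists passed with an estimated correlation (adjusted p from 0.239 to 0.524). OAS1 had 5.54 CPM in NL and 37.7 CPM in JPS (log2 fold change 2.77 ± 0.40, adjusted p = 0.0677, n = 3 per group), and COL3A1, a fibrillar collagen, had 153 ± 5.47 and 974 ± 282 CPM (2.67 ± 0.47, adjusted p = 0.0926). No single gene passed: the count was 0 with edgeR, 1981 genes had an unadjusted p under 0.05, and the count was 744 with DESeq2 and 499 with limma-voom. The edgeR count was 1 without NL replicate 2 and 1 without JPS replicate 2. Without both it was 16, among them FKBP5 (-4.60 ± 0.40) and OAS1 (2.69 ± 0.28). The groups did not overlap in 16.4% of genes, where chance gives 10%.

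Camera passed 18 lists in JPS against NL, 12 higher and 6 lower, and in every list 0 genes passed over all genes tested. Of 25 interferon response genes, 10 were higher adjusted over the list alone, with a median of 1.20 (camera adjusted p = 1.30e-11, and adjusted p = 0.239 with an estimated correlation). Of 17 foveolar markers, 2 were higher adjusted over the list alone, GPX2 (3.17 ± 0.56) and TFF1 (3.07 ± 0.86), with a median of 1.68 (camera adjusted p = 2.39e-07, and adjusted p = 0.431 with an estimated correlation). Of 21 inflammation genes, 13 were higher and 3 lower adjusted over the list alone, with IL1RN at 3.19 ± 0.59, IL1B at 4.20 ± 0.90 and NFKBIA at -1.94 ± 0.46 (camera adjusted p = 2.12e-06, and adjusted p = 0.239 with an estimated correlation). Of 20 fibroblast and matrix genes, 8 were higher and 2 lower adjusted over the list alone, with COL5A1 at 2.19 ± 0.42 (camera adjusted p = 0.00131, and adjusted p = 0.431 with an estimated correlation). The fibroblast list had an adjusted p of 0.0941 on FPKM with 1 added, its median of 0.92 was 0.37 without JPS replicate 1, and JPS replicates 1 and 3 lay below NL replicate 2 (median log2 CPM of 6.11 and 6.18 against 6.75). Of 11 enteric neuron and glia markers, 2 were lower adjusted over the list alone, with UCHL1 at -3.45 ± 0.91 and RET at -3.19 ± 0.87 (camera adjusted p = 9.55e-06, and adjusted p = 0.239 with an estimated correlation). Of 16 endocrine markers, SST, at -2.92 ± 0.58, was the 1 lower adjusted over the list alone (camera adjusted p = 1.32e-05, and adjusted p = 0.524 with an estimated correlation). The endocrine libraries overlapped, with median log2 CPM of 2.90, 1.76 and 2.01 in NL and 0.71, -3.75 and 2.04 in JPS, and the median log2 fold change of -1.45 was -0.92 without JPS replicate 2 and -2.85 without JPS replicate 3.

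Among the genes fixed for all comparisons, TGFA had 1.05 ± 0.62, MUC5AC 1.68 ± 1.15, PGC -3.54 ± 1.51, ATP4A -1.44 ± 1.94, ATP4B -0.90 ± 1.94, EGFR -0.54 ± 0.79, GLI1 0.72 ± 0.64 and PTCH1 0.73 ± 0.49 in JPS against NL, and none passed. ATP4A and ATP4B were -3.92 and -3.93 without JPS replicate 3, PGC was -2.05 without NL replicate 2, and EGFR was -0.019 without JPS replicate 2 and -1.46 without JPS replicate 3. SMAD4 and BMPR1A, in which inherited variants are a known cause of JPS, had -0.47 ± 0.47 and -0.0098 ± 0.38, and BMPR1A turned positive without NL replicate 1 (0.089), NL replicate 3 (0.22) or JPS replicate 1 (0.11). The mitochondrially encoded list was higher in JPS (median 3.33, camera adjusted p = 0.00704, and adjusted p = 0.625 with an estimated correlation) and turned lower without JPS replicate 2 (adjusted p = 0.0334).

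MD was compared with JPS because the design sets these disorders beside each other. Foveolar markers were higher in MD than in JPS in 17 of 17 genes, with TFF1 at 7072 ± 775 CPM in MD and 1964 ± 874 CPM in JPS (SD, n = 3 per group) and DPCR1 at a log2 fold change of 2.74 ± 1.12. EGF receptor ligands and receptors were higher in 11 of 11 genes, with AREG at 2.81 ± 1.02 and TGFA at 1.05 ± 0.62. REG4 had 190 ± 158 CPM in MD and 12.5 ± 9.17 in JPS (3.93 ± 0.89), and CEACAM5 had 653 ± 545 and 48.8 ± 12.5 (3.74 ± 0.89). No single gene passed: the count was 0 with edgeR, 474 genes had an unadjusted p under 0.05, and the count was 15 with DESeq2 and 1 with limma-voom. Without NL replicate 2 and JPS replicate 2 the count was 1, the cystine transporter gene SLC7A11 (2.50 ± 0.19, adjusted p = 0.0390), named after its values were seen. The groups did not overlap in 11.2% of genes, where chance gives 10%.

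In MD against JPS, camera passed 13 lists, 7 higher and 6 lower, and in every list 0 genes passed over all genes tested. Each of the 13 lists had an adjusted p = 0.602 with an estimated correlation. The foveolar list had a median of 1.56 with 0 genes adjusted over the list alone (camera adjusted p = 2.99e-05), and the list of EGF receptor ligands and receptors had a median of 0.72 with 1 gene higher adjusted over the list alone (1.03e-04). That median of the EGF receptor list was 0.22 without JPS replicate 2, 1.14 without JPS replicate 1 and 1.22 without JPS replicate 3. Of 16 Notch pathway genes, 16 had positive values and 0 passed adjusted over the list alone, with JAG1 at 1.70 ± 0.47 (camera adjusted p = 0.00932, and 0.0580 without MD replicate 3). Parietal markers had a median of -1.13 with 0 genes adjusted over the list alone (6.36e-05, and 0.325 without MD replicate 3). The MD and JPS libraries overlapped for this parietal list, and its median was -2.31 without MD replicate 1, -0.59 without MD replicate 3 and turned positive, at 0.60, without JPS replicate 3. Mitochondrially encoded genes were lower in MD in 13 of 13 genes, all 13 adjusted over the list alone, with a median of -5.10 (1.48e-16), which was -1.07 without JPS replicate 2 (3.59e-11). Of the other genes fixed for all comparisons, MUC5AC had 1.82 ± 1.16, EGFR 0.60 ± 0.79, PGC -0.70 ± 1.38, ATP4A -1.38 ± 1.94, ATP4B -1.38 ± 1.96, SMAD4 -0.048 ± 0.47, BMPR1A -0.10 ± 0.38, GLI1 -0.17 ± 0.62 and PTCH1 -0.15 ± 0.49, and none passed. EGFR was 0.051 ± 0.32 without NL replicate 2 and JPS replicate 2. Without JPS replicate 3, ATP4A, ATP4B and SMAD4 turned positive (1.11, 1.66 and 0.44), as did SMAD4 without MD replicate 3 (0.23). GLI1 turned positive without MD replicate 2 (0.14) or JPS replicate 2 (0.21), PTCH1 without MD replicate 2 (0.10), and BMPR1A without MD replicate 3 (0.023) or JPS replicate 3 (0.0016).

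A gene that sets MD apart from both other groups would pass in MD against NL and in MD against JPS. The number of such genes was 0 with edgeR, where MD against JPS itself had 0, and it was 11 with DESeq2 and 1 with limma-voom. The log2 fold changes of MD and JPS relative to NL had a Pearson r of 0.841 and a Spearman rho of 0.797 across 17980 genes, which are not independent replicates. Since both comparisons share the NL libraries, unchanged groups simulated 20 times gave a mean r of 0.511, from 0.495 to 0.527. The simulated covariance was 0.277 against 1.32 observed. Genes were drawn independently in the simulation, so it cannot show how far r varies when genes or whole libraries move together. Of 100 splits of the 9 libraries, 7, the real one among them, gave an r as high, so chance cannot be excluded for it. The sign was the same in both comparisons in 80.2% of genes, against a mean of 66.8% in the simulations. The r was 0.715 without JPS replicate 1 and 0.770 without JPS replicate 3.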

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

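The fits without NL replicate 2 and JPS replicate 2 together and without mitochondrially encoded genes were chosen after the data were seen. The count of genes changed in MD against NL was 338 and moved by over 1.5 times at an adjusted p of 0.01 (8), with no low-count filter (721), DESeq2 (1820), limma-voom (5168), and limma on log2 FPKM with 1 (736) or 0.1 (209) added; leaving out libraries gave 6 to 1777. With RLE factors it was 293, with upper-quartile factors 290, with the stricter filter 265, with only the groups compared 352, and with the replicate number as a block 295, of which 239 were among the 338. In JPS against NL the count of 0 with edgeR, with 1981 genes at an unadjusted p under 0.05, became 169 with no filter, 744 with DESeq2, 499 with limma-voom, 98 and 11 on FPKM, and 0 to 16 without libraries. In MD against JPS the count of 0, with 474 genes at an unadjusted p under 0.05, became 15 with DESeq2, 1 with limma-voom, 29 and 1 on FPKM, and 0 to 1 without libraries. Genes changed in MD against both groups numbered 11 with DESeq2, 1 with limma-voom, 29 and 1 on FPKM, and 0 to 1 without libraries. The FPKM values had no TMM scaling, and the TMM factor was 0.169 in JPS replicate 2 against 1.36 to 1.62 in MD. On FPKM all 29 and 1 calls of MD against JPS were higher in MD, and the median of all genes moved by 0.663 and 1.03. These FPKM counts cannot be told apart from that shift. Lists past the threshold fell from 22, 18 and 13 to 0, 0 and 0 with an estimated correlation and to 6, 1 and 0 with fry. The Hedgehog list in JPS against NL passed with limma-voom (adjusted p = 0.00850), and its adjusted p ran from 0.00852 to 0.334 without libraries. In MD against JPS its direction turned on FPKM with 1 added (0.896), with fry (0.871) and without MD replicate 3 (0.849), and its adjusted p ran from 0.160 to 0.850 without libraries. The correlation of fold changes was 0.698 with no filter, 0.707 with DESeq2, 0.771 on FPKM with 1 added, and 0.715 to 0.870 without libraries. In MD against NL, EGFR was -0.043 with RLE, -0.060 with upper-quartile factors, -0.026 with the stricter filter, -0.039 with DESeq2, -0.34 with limma-voom, -0.041 without mitochondrially encoded genes, and -0.39 to 0.38 without libraries. SMAD4 was 0.042 and 0.091 on FPKM, and BMPR1A was 0.45 and 0.58 on FPKM and -0.41 to 0.12 without libraries. For these changes the cause was not tested. Of 650 refits of the 31 genes named in MD against NL, 521 kept direction and side of the threshold, 102 lost the call, 12 gained it and 15, of 3 genes, changed sign. Among other list members the sign changed in 30 of 2142 refits (8 of 103 genes) in MD against NL, 25 of 2103 (8 of 101 genes) in JPS against NL and 97 of 1710 (32 of 82 genes) in MD against JPS. The median log2 fold change of all genes moved by more than 0.1 in MD against NL with RLE (-0.118), upper-quartile factors (-0.135), no filter (0.101), DESeq2 (-0.118), limma-voom (-0.112), FPKM (0.562 and 0.668) and without both libraries (-0.111); in JPS against NL on FPKM (-0.161 and -0.340) and without JPS replicate 2 (0.184); and in MD against JPS with upper-quartile factors (-0.126), limma-voom (-0.118), FPKM (0.663 and 1.03), and without JPS replicate 2 (-0.187) or both libraries (-0.199). At this depth and spread, simulated 2-fold changes were not recovered (0 of 50 in each comparison).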

Other observations

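The tests of NL replicate 2 and of the stromal share for glucocorticoid-induced genes, the 84 splits of the libraries for those genes, and both tests for SHH were chosen after the result was seen; the 21 further glucocorticoid-induced genes were chosen after the pattern but before their values. Some gene groups were not described with the comparisons. In MD against NL, PDX1, a transcription factor of the antrum and duodenum, rose by 4.90 ± 0.75 and IRX3 fell, at -3.03 ± 0.63, while of 11 regional markers 1 rose and 1 fell over all genes tested, and 2 were higher and 1 lower adjusted over the list alone. That list did not pass camera, which ranked it lower (adjusted p = 0.887), with a negative median of -0.081 and a positive mean of 0.68. Its direction in camera turned in 9 of 20 alternative fits. The median was 0.43 without NL replicate 2 and 0.23 without MD replicate 1. HES1, a Notch target, rose by 2.11 ± 0.36, the glucose transporter SLC2A1 rose by 3.48 ± 0.58, and ANO1, a chloride channel, rose by 3.04 ± 0.61. KLF4 rose by 2.56 ± 0.38 and NR4A1 fell, at -2.54 ± 0.54, both early-response genes. Each of these 7 genes lost its call without NL replicate 1, with adjusted p from 0.0890 (PDX1) to 0.140 (ANO1), and all 7 lost it without at least 1 further library. The sampling site within the stomach was not given in the sources used here, and a difference in site between the groups was not tested and stays open for PDX1, IRX3 and the chief and parietal markers. WIF1, a WNT inhibitor, had 3.54 CPM in NL, 0.0522 CPM in MD and 0.0393 CPM in JPS.

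Genes induced by glucocorticoids had lower values in MD and JPS than in NL. Of 21 further such genes, 3 fell over all genes tested in MD against NL and 0 passed in JPS against NL. Negative values were found for 19 in MD against NL (median -2.15, camera p of 1.43e-13, and 0.00200 with an estimated correlation) and for 20 in JPS against NL. This test is consistent with higher glucocorticoid exposure of the NL tissue, a hypothesis found and tested on the same libraries. Without NL replicate 2, FKBP5, TSC22D3, PER1, KLF15 and ZBTB16 had a median of -3.77. These 5 genes were picked on the same libraries, and each NL library lay above all others in them, so this cannot decide on NL replicate 2. Of the 21 further genes, 20 had negative values in MD against NL without NL replicate 2 and JPS replicate 2 (median -1.77). This argues against NL replicate 2 as the whole source for those 21 genes. A lower share of smooth muscle or endothelial cells as the whole source is argued against by the medians of these lists. They were -0.97 ± 0.94 (SD over genes) and -0.15 ± 0.73. The fibroblast and matrix list had 0.90 ± 1.81. Its members VCAN and COL3A1 rose while C7 and COL14A1 fell, so its median cannot decide on the share of fibroblasts. Of the 84 splits of the 9 libraries into 3 and 6, 1, the real split, gave an excess of the 21 genes as large as the 2.02 of NL (highest other 1.22), which describes values already seen and excludes nothing. Treatment, time of day, fasting, sampling site and a lower share of fibroblasts, neurons or adipocytes stay open. So does the epithelial makeup, which was not tested for these genes. Chief cell markers had a median of -2.99 and foveolar markers 3.23 in MD against NL.

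SHH rose in MD against NL while GLI1 and PTCH1 did not pass. A higher share of surface mucous cells is a candidate explanation that the test cannot decide. The log2 fold change of SHH lay 1.23 below that of the highest foveolar marker (a difference of -1.23), and 6 of 17 foveolar markers lay above SHH. Those markers ran from 0.38 to 4.92, a range so wide that lying within it is weak support. Within MD, SHH was 77.4, 102 and 156 CPM in replicates 1 to 3, while the foveolar median log2 CPM was 9.70, 9.82 and 9.65. On log2 CPM, SHH minus the foveolar median was -3.93, -1.68 and -4.07 in NL and -3.43, -3.15 and -2.36 in MD. The MD values lay within the NL range, whose upper end was NL replicate 2. Too few counts to see a rise of the size of SHH in both genes is argued against by the upper 95% bound for PTCH1, 1.66, below the lower bound for SHH, 2.17. Smaller rises stay open, since the upper bound for GLI1 was 1.92 and 7 of 50 simulated 4-fold changes were called. Of 14 Hedgehog target genes, FOXL1 rose over all genes, and 3 were higher and 2 lower adjusted over the list alone. Signalling that acts on few cells stays open and was not tested.

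The 30 ribosomal protein genes had negative values in MD against NL, with 0 past the threshold over all genes and 0 adjusted over the list alone (median -1.68, camera adjusted p = 2.05e-06, and adjusted p = 0.584 with an estimated correlation). Without NL replicate 2 the median was -0.093 and the adjusted p 0.293, within a range of 8.67e-11 to 0.584 over the alternatives, so that library may account for most of the difference. Gene length is argued against as the whole cause by a median of -1.50 after a correction for length. No biological explanation was tested.

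Other splits of the libraries were counted for each result. In MD against NL, 1 of 10 splits gave as many genes (338, highest other 0), 1 gave as many lists (22, highest other 20), and 6 gave a Hedgehog list p as small (0.277, smallest other 0.00745). In JPS against NL, 10 gave as many genes (0, highest other 0), 1 as many lists (18, highest other 15) and 1 as small a Hedgehog p (0.0659, smallest other 0.0849). In MD against JPS, 10 gave as many genes (0, highest other 0), 6 as many lists (13, highest other 20) and 7 as small a Hedgehog p (0.561, smallest other 0.0420). Splits of 3 against 3 are too few for a share under 0.05. Of 100 splits of the 9 libraries, 7 gave a correlation as high (0.841, highest other 0.888), so chance cannot be excluded for it. For genes changed against both groups 100 of 100 gave as many (0, highest other 1), which a count of 0 fixes in advance, as it does in JPS against NL and MD against JPS, so these splits say nothing.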
